A study of Mus musculus with 2 samples.

How the data were processed

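Long-read RNA-seq had been run on 2 libraries of left cerebral cortex from heterozygous female 5xFAD mice, per the labels. The labels number them biological replicates 1 and 2 and give no other group, so both formed 1 group and no conditions were compared. They list separate tissue samples but 1 shared donor record, give no age, and name the sex in a free-text description while the field for it is unfilled. No label says that the tissue came from separate animals, so p-values measure only the difference between these libraries, which may be technical.

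The deposited values are counts, whole numbers of long reads assigned to each transcript model, with no normalization. Per the file headers and the notes deposited beside them, each library was processed on its own from 1 filtered alignment to mm10 and annotated against GENCODE M21, and the attributes of the annotation files name TALON. The aligner, the read filters and the handling of strand are not given in the sources used here. Each deposited count comes with an annotation class: known, incomplete splice match (ISM), unannotated combination of annotated splice sites (NIC), unannotated splice site (NNC), antisense, intergenic or genomic. Because classes were given in each library separately, the same chain of introns could be classed differently in each, which was so for 4305 of 65696 shared chains with 1.24% of their reads. The annotation holds mouse genes, so an aligned read of a human transgene could be counted only under a mouse gene or outside genes. Spike-in reads (SIRV and Ambion mix 1, per the labels) were left out of all totals after their share was recorded.

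Reads were summed per annotated gene over the known, ISM, NIC, NNC and genomic models assigned to it. Gene totals were 1932130 in replicate 1 and 1477352 in replicate 2, and CPM is the count per 1000000 of these. Single-read transcripts were 64.1% and 64.3% of those listed. A count of 0 was given an upper limit of 3 reads, and shares of 1 library have exact Clopper-Pearson 95% intervals. The reads carry no molecular identifiers in the files, so intervals and floors cover counting error only.

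The planned tests and their filters, the rule for naming genes, 23 gene lists and most alternatives were fixed before the data were examined. Added later were the test of the share of App reads with the Kunitz exon, the exact intervals of ratios of single genes, the alternatives named below, the further olfactory markers and the tests of the closing section. Genes with at least 10 reads over both libraries were compared by a two-sided exact binomial test against the gene totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios are replicate 2 over replicate 1 with 0.5 added to each count, and their standard errors cover counting only. Correlations used log2(CPM + 1), set beside the mean of 20 draws with counting error alone. The biological coefficient of variation was the square root of edgeR's common dispersion after TMM scaling in a model with an intercept only. Since 1 group has no contrast, edgeR's quasi-likelihood test could not be applied, and edgeR's negative binomial exact test with that dispersion served as an alternative. The dispersion came from the same libraries it was used to compare, so any real difference between them enters it.

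The lists were Alzheimer risk and pathology, amyloid transgene, plaque-associated (DAM) microglia, homeostatic microglia, complement, interferon response, MHC and antigen presentation, astrocyte, reactive astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, excitatory neuron, inhibitory neuron, synapse, vascular and mural, choroid plexus with ependyma and meninges, neighbouring brain regions, blood, immediate early genes, mitochondrially encoded, long noncoding RNA, sex-linked, and isoform. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins, and read against the percentiles 2.5 and 97.5 as a description of these libraries. Members past the test were also counted after adjustment over the list alone.

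Isoform usage was compared in genes with at least 20 reads in each library over at least 2 isoforms of 5 or more reads, using known, NIC and NNC multi-exon chains. A chi-square statistic was tested by Monte Carlo permutation of reads with 100000 draws, so the smallest p was 1e-05. Unannotated chains were matched between libraries by chromosome, strand and introns. Cassette inclusion was the share of reads holding both junctions of an exon among those and the reads that skip it, for 1 pair of flanking splice sites at a time, in events with at least 10 such reads in each library, tested two-sided by Fisher's exact test. Reads that hold the exon beside other neighbouring exons are left out of an event, so for the Kunitz exon of App the share among all reads that hold it or span it with 1 intron was added. Exons of 27 nt or less were called microexons.

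Genes were named by rule. In each list these were the 3 members highest by mean CPM and every member past the test, with values for at most 4. The others were the 10 most abundant nuclear and 5 mitochondrially encoded genes, and among genes past the test the 10 with the largest log2 ratios in each direction. For isoforms they were the 25 genes of the isoform list with the most full-length reads plus fixed additions, the 10 unannotated chains with the most reads found in both libraries, and the 10 genes with the smallest p for isoform usage. The rule also took at most 12 cassette exons of the isoform list, the 10 microexons with the most reads, and 5 intergenic and 5 antisense loci. App, Psen1 and Thy1 were described in full. The values of 1 gene that the rule takes are not reported here. Genes named outside this rule, such as C4a, Bhlhb9 and genes with high single-exon shares, were chosen after their values were seen. The olfactory markers were listed after the values of Omp, Th and Doc2g had been seen and before their own were.

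The tests were run on simulated data with known answers. Among 12920 genes drawn with the depths of these libraries, the binomial test recovered 17.5% of 63 genes changed 1.5-fold, 50.7% of 67 changed 2-fold and 74.3% of 70 changed 4-fold, and called 4 of 12727 unchanged genes. Over 4618 simulated genes, the isoform test recovered 78.5% and the inclusion test 79.5% of 200 genes moved by 30 percentage points. They called 3 and 11 of 4418 unchanged genes. The inclusion test was run here on the 4618 simulated genes and not on cassette events. Its recovery among the 20188 events compared below, which have a different read minimum, was therefore not tested. Lists shifted by 0.5 on the log2 scale passed in 20 of 20 draws and unshifted lists in 1 of 20. In that check the ratios of genes were drawn independently, with the same spread at all expression levels. Members of real lists can vary together, so the rate for unshifted lists may not hold for them. A simulated coefficient of variation of 0.1 was estimated at 0.0993 and one of 0.2 at 0.194.

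Alternatives planned beforehand were TMM and DESeq2 scaling, no low-count filter, at least 50 reads, other pseudocounts, known transcripts only, thinning of replicate 1 to the depth of replicate 2, and edgeR's negative binomial test. For transcripts they were inclusion or removal of ISM reads, higher read minimums, splice sites within 10 bases, and leaving out each replicate. Added after seeing the data were counting genes with overlapping exons on the same strand as 1 locus, removal of the trend of the ratio with transcript length (lowess, fraction 0.3) and taking a chain's class from either library. Scaling moved little, with TMM factors of 1.00048 and 0.999523 and a median log2 ratio of −0.00. The log2 ratio rose with known transcript length (Spearman rho = 0.161 across 7914 genes, which are not independent), from a median of −0.26 under 1000 nt to 0.08 above 5000 nt. Reads themselves, the human transgene sequences and the genome sequence were not used here. The software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.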

Results

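Long-read RNA sequencing was run on the left cerebral cortex of heterozygous female 5xFAD mice, a strain that carries mutant human APP and PSEN1 transgenes under the control of the neuronal Thy1 promoter and develops amyloid plaques. The 2 libraries, biological replicates 1 and 2, formed 1 group. Replicate 1 held 1976211 reads and replicate 2 held 1507250 reads, of which 1932130 and 1477352 were assigned to annotated genes. One read therefore stood for 0.518 CPM (counts per 1000000 annotated-gene reads) in replicate 1 and 0.677 CPM in replicate 2, and a count of 0 allows up to 1.55 CPM and 2.03 CPM. Spike-in RNA took 0.0441% of the reads in replicate 1 (exact Clopper-Pearson 95% interval 0.0412–0.0472%) and 0.0569% in replicate 2 (0.0531–0.0608%). Intervals and floors cover counting error only. No control group was analysed here, so the tests below compare the 2 libraries and no conditions.

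The most abundant nuclear transcripts of the cortex came from Hspa8, a constitutive heat shock protein, at 12502 ± 549 CPM (mean ± SD, n = 2). Mbp, which encodes myelin basic protein, followed with 8385 ± 617 CPM, and the creatine kinase gene Ckb with 8245 ± 90.6 CPM. The lysosomal protease gene Ctsd stood at 7915 ± 2.72 CPM and Apoe, the main lipid carrier of astrocytes and activated microglia, at 7641 ± 193 CPM. Fth1, Tuba1a, Eef1a1, Eef2 and Trf completed the 10 most abundant nuclear genes with 6101 ± 890, 5094 ± 272, 4443 ± 133, 4381 ± 173 and 4291 ± 876 CPM. Together these 10 genes took 6.91% of annotated-gene reads in replicate 1 and 6.89% in replicate 2. Counts on mitochondrially encoded genes were far lower, with mt-Co1 at 427 ± 128 CPM, mt-Rnr2 at 176 ± 13.6, mt-Cytb at 57.1 ± 10.8, mt-Nd4 at 37.0 ± 9.20 and mt-Nd5 at 27 ± 0.115 CPM. The read filters are not given, so these counts cannot be read as the abundance of mitochondrial transcripts in the cortex. Hspa8, Tuba1a, Eef1a1, Ctsd, Trf and mt-Nd4 overlap other annotated genes on the same strand, and Tuba1a and Eef1a1 have near-identical copies, so these counts are uncertain.

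App, which encodes the amyloid precursor protein, was higher in replicate 2, with 1897 CPM against 1090 CPM in replicate 1, a log2 ratio of 0.80 ± 0.04 (counting standard error; exact binomial test, adjusted p = 8.26e-80). With the spread between the libraries added to counting error, edgeR's negative binomial exact test gave App an adjusted p of 0.228. Psen1, the catalytic subunit of gamma-secretase, stood at 77.1 and 105 CPM, and Thy1, a neuronal surface glycoprotein whose promoter drives the transgenes, at 54.3 and 41.3 CPM. Their exact binomial adjusted p-values were 0.119 and 0.486. These 3 genes form the amyloid transgene list, in which 1 of 3 measured members passed the test over all genes and 2 when adjusted over the list alone. The list had a median log2 ratio of 0.44, at percentile 98.9 of 10000 random lists matched on expression. With 3 members this median is the ratio of Psen1 alone, and Thy1 had the lower value in replicate 2. The percentile therefore shows no shift of the list as a whole. The annotation holds mouse genes, and reads of the human transgenes have no gene of their own in it.

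The App gene (ENSMUSG00000022892.11) lies on chromosome 16 of mm10 from 84949685 to 85173766. Its 16-exon transcript App-201 took 94.3% of full-length App reads in replicate 1 and 91.4% in replicate 2 (mean 92.9 ± 2.01%, SD, n = 2), and the 17-exon App-202 took 1.64 ± 0.485%. The 168-nt exon at 85043576–85043743, which encodes the Kunitz protease inhibitor domain, was held by 62 of the 2036 reads across it in replicate 1 (3.05%, exact Clopper-Pearson 95% interval 2.34–3.89%) and by 137 of 2690 in replicate 2 (5.09%, 4.29–5.99%). This share, computed after the inclusion values were seen, had a Fisher's exact test p of 0.000557 with no adjustment. In the planned count, of reads that join the flanking exons of App-201 either directly or through this exon alone, inclusion was 1.75% of 2004 and 3.35% of 2629 (Fisher's exact test over all events, adjusted p = 1). App was among the genes whose isoform proportions differed between the libraries (Monte Carlo permutation test, adjusted p = 0.00084), but not once transcript classes were matched between the libraries, as described for isoform usage below.

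Psen1 (ENSMUSG00000019969.14, chromosome 12 of mm10, 83688152–83735199) was represented mainly by the 12-exon Psen1-201, with 89.5 ± 2.71% of full-length reads (SD, n = 2). A 10-exon incomplete model of Psen1 held 9 reads in replicate 1 and 3 in replicate 2. It ran from 83699601 to 83733981 in replicate 1 and to 83733980 in replicate 2, from 36 bases after the start of the coding region to 90 bases before its end. Thy1 (ENSMUSG00000032011.5, chromosome 9 of mm10, 44043384–44048579) had the 4-exon transcript Thy1-201 with 47 reads in replicate 1 and 15 in replicate 2. Single-exon models on its last exon, which holds the 3' untranslated region, held 50.5% of 105 Thy1 reads in replicate 1 (exact Clopper-Pearson 95% interval 40.5–60.4%) and 70.5% of 61 in replicate 2 (57.4–81.5%). These started at 44047922 in replicate 1, with 53 reads, and at 44047339 in replicate 2, with 42 reads.

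**Figure D1:**
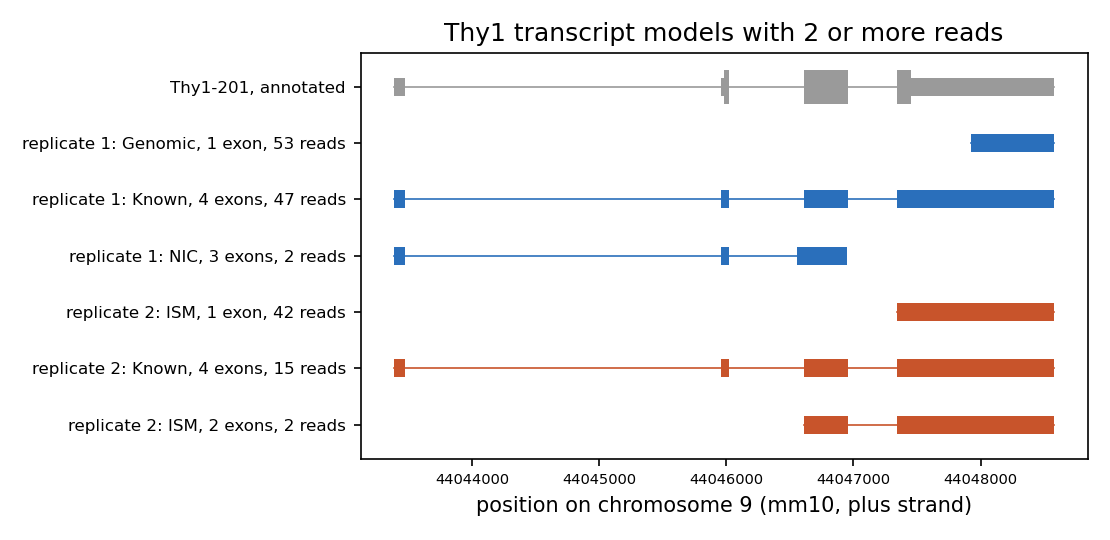
Transcript models of Thy1 with 2 or more reads along chromosome 9 (mm10, position in bases), with exons as boxes, introns as lines and the coding part of the annotated Thy1-201 drawn taller. Single-exon models with 53 reads in replicate 1 and 42 reads in replicate 2 lie within the last exon.

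Of the 33 measured genes of Alzheimer risk and pathology, 6 were higher in replicate 2 and 1 was higher in replicate 1, and 10 passed when adjusted over the list alone. Besides App, the chaperone clusterin gene Clu was higher in replicate 2 (548 and 712 CPM, log2 ratio 0.38 ± 0.06, adjusted p = 2.68e-07), as was the lysosomal progranulin gene Grn (166 and 240 CPM, 0.53 ± 0.11, adjusted p = 0.00013, exact binomial tests). Aplp1, Aplp2 and Ctsb were also higher in replicate 2, and Itm2b, at 1912 and 1734 CPM, was higher in replicate 1. Ctsd and Apoe, the most abundant members, differed by −0.00 and −0.05 on the log2 scale and did not pass. The list's median log2 ratio was 0.10, at percentile 95.6.

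Plaque-associated (DAM) microglial genes went both ways. Of 28 measured, Ctsz and Ctsb were higher in replicate 2 while Spp1, which encodes osteopontin, and the iron storage gene Fth1 were higher in replicate 1, and 7 passed when adjusted over the list alone. The log2 ratio of Fth1 was −0.30, and −0.12 with the trend on transcript length removed. Spp1 had 234 CPM in replicate 1 and 96.1 in replicate 2, a log2 ratio of −1.28 ± 0.14 (exact binomial test, adjusted p = 3.55e-20). The median was −0.08, at percentile 10.1. It was −0.03 (percentile 30.1) with at least 50 reads and −0.0009 (percentile 50.95) with the trend on transcript length removed. Homeostatic microglial genes included Csf1r (253 and 414 CPM), Fcrls (220 and 326 CPM) and the fractalkine receptor Cx3cr1 (148 and 199 CPM), all higher in replicate 2, and no other of the 17 measured passed over all genes or when adjusted over the list alone. Their most abundant member was Hexb at 1746 ± 56.7 CPM (SD, n = 2), and their median log2 ratio of 0.10 lay at percentile 90.2.

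Among 9 measured complement genes, C4b (81.3 and 156 CPM, log2 ratio 0.94 ± 0.15, exact binomial adjusted p = 4.75e-08) and Clu were higher in replicate 2, and the same number, 2, passed when adjusted over the list alone. C1qa and C1qb stood at 259 ± 25.6 and 207 ± 26.6 CPM (SD, n = 2), and the median log2 ratio was 0.33, at percentile 99.2. Reads of C4b cannot be told apart with certainty from those of its near-identical copy C4a, which had 2 and 0 reads. No interferon response gene of 12 measured and no MHC or antigen presentation gene of 12 measured passed, either over all genes or when adjusted over the list alone. Ifit3, Stat1 and Ifit1 stood at 169 ± 5.78, 75.9 ± 12.3 and 48.4 ± 6.22 CPM, and the interferon median of 0.10 lay at percentile 79.1. H2-D1, B2m and H2-K1 stood at 447 ± 34.6, 163 ± 11.5 and 119 ± 17.8 CPM, and the median of 0.01 lay at percentile 53.6.

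Of 18 measured astrocyte genes, 7 were higher in replicate 2, 1 was higher in replicate 1 and 10 did not pass, and 10 passed when adjusted over the list alone. Atp1a2, the astrocytic sodium pump, stood at 511 and 963 CPM (log2 ratio 0.91 ± 0.06, adjusted p = 3.04e-50), and the glutamate transporter Slc1a2 at 195 and 364 CPM (0.90 ± 0.10, adjusted p = 2.29e-18, exact binomial tests). Sparcl1, Slc1a3, Aldoc, Aldh1l1 and Glul were also higher in replicate 2, whereas Cst3 was higher in replicate 1 with 2229 against 1673 CPM (log2 ratio −0.41, and −0.21 with the trend on transcript length removed). The list's median was 0.14, at percentile 98.4. Of 12 measured reactive astrocyte genes, 6 were higher in replicate 2 both over all genes and when adjusted over the list alone, and their median of 0.54 lay at percentile 100. They were Gfap, the glial intermediate filament (2260 and 2900 CPM), Vim (99.4 and 164), Serpina3n (30.0 and 63.0), Gbp2 (22.3 and 44.7), Ptgds and C4b.

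Vascular and mural genes had the largest list median, 0.68, at percentile 100, and 7 of 16 measured were higher in replicate 2, with 9 when adjusted over the list alone. With at least 50 reads their median was 0.539, just below the 0.543 of reactive astrocyte genes. The endothelial genes Slco1a4, Pecam1 and Cldn5 stood at 43.5 and 97.47, 12.4 and 34.5, and 154 and 223 CPM in replicates 1 and 2. Bsg, Vtn, Rgs5 and the smooth muscle actin gene Acta2 were the others, and Itm2a stood at 180 ± 5.00 CPM. Choroid plexus, ependyma and meninges genes had a median of 0.40, at percentile 99.0, and 2 of 9 measured passed over all genes and 2 when adjusted over the list alone. Enpp2 stood at 465 and 615 CPM, and Ttr, the transthyretin gene of choroid plexus, at 347 and 432 CPM. Igfbp2 followed at 49.3 ± 9.72 CPM. In the oligodendrocyte and myelin list, Mbp, Trf, Cnp, Cldn11 and Mag were higher in replicate 2, making 5 of 20 measured, with 8 when adjusted over the list alone. Trf, which encodes transferrin, showed the largest of these ratios at 3671 and 4910 CPM, Plp1 stood at 2326 ± 46.1 CPM, and the median was 0.03, at percentile 68.2. Of 8 measured oligodendrocyte precursor genes none passed over all genes or when adjusted over the list alone, with Olig1, Olig2 and Gpr17 at 169 ± 8.21, 94.3 ± 14.1 and 20.0 ± 4.20 CPM and a median of 0.37, at percentile 97.9. That median lay inside the bounds set on the random lists with at least 50 reads (percentile 94.4) and with the trend on transcript length removed (percentile 96.4).

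Of 18 measured excitatory neuron genes, Camk2a was higher in replicate 2 (360 and 482 CPM) and the calcium sensor gene Hpca in replicate 1 (1194 and 1044 CPM), and 2 passed when adjusted over the list alone. Chn1 was the most abundant at 2262 ± 91.6 CPM, and the median was −0.04, at percentile 31.9. Gad1, which makes the inhibitory transmitter GABA, was higher in replicate 1 with 832 against 602 CPM (log2 ratio −0.47 ± 0.06, exact binomial adjusted p = 1.3e-12). Dlx1, an interneuron transcription factor, was also higher there with 36.7 against 15.6 CPM. These were the 2 of 15 measured inhibitory neuron genes past the test, 3 when adjusted over the list alone. Calb1 and Slc6a1 stood at 368 ± 12.2 and 242 ± 8.41 CPM, and the median was −0.16, at percentile 6.86, against −0.09 at percentile 18.9 with the trend on transcript length removed. Among 27 measured synapse genes, the vesicle fusion gene Vamp2 was higher in replicate 1 (601 and 350 CPM, log2 ratio −0.78 ± 0.08, exact binomial adjusted p = 5.08e-23), as were Cplx1 and Snap25. Stx1a and the glutamate receptor gene Gria3 were higher in replicate 2. In all 7 synapse genes passed when adjusted over the list alone, Syp and Stxbp1 stood at 1284 ± 63.0 and 961 ± 52.2 CPM, and the median was 0.09, at percentile 93.8.

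Genes of neighbouring brain regions included the striatal markers Ppp1r1b at 605 ± 10.3 CPM and Penk at 332 ± 24.8 CPM. Doc2g, which is abundant in olfactory bulb output neurons, had 109 reads in replicate 1 and 19 in replicate 2 (log2 ratio −2.10 ± 0.35, exact binomial adjusted p = 2.11e-09). Th, the tyrosine hydroxylase of dopaminergic neurons, had 64 and 9 reads (−2.38 ± 0.50, adjusted p = 1.95e-06, exact binomial test), and Adora2a, a striatal marker, had 280 and 142. These 3 of 17 measured were higher in replicate 1, 5 when adjusted over the list alone, and the median of −0.14 lay at percentile 7.36. Of 20 further olfactory bulb markers, chosen after these values were seen, 12 were measured and all 12 had the higher value in replicate 1 (median log2 ratio −0.62), the library in which Gad1 and Dlx1 were also higher. The activity-regulated genes Arc (156 and 219 CPM) and Egr1 (71.9 and 106 CPM) were the 2 of 16 measured immediate early genes higher in replicate 2, with 3 when adjusted over the list alone. Junb and Jun stood at 256 ± 1.44 and 91.1 ± 14.7 CPM, and the median was 0.09, at percentile 81.3, against −0.09 at percentile 15.8 with at least 50 reads.

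Mitochondrially encoded genes had the lowest list median, −0.60, at percentile 0.01. Of 11 measured, mt-Co1 (518 and 336 CPM) and mt-Co3 (48 and 10 reads) were higher in replicate 1, and 2 passed when adjusted over the list alone. Reads on all mitochondrially encoded genes took 0.0964% of annotated-gene reads in replicate 1 and 0.0686% in replicate 2. Since the read filters are not given, these counts and the list's median may not stand for the cortex. Among 13 measured long noncoding RNAs, the imprinted Meg3 (931 and 627 CPM) and Snhg11 (249 and 198 CPM) were higher in replicate 1, 2 passed when adjusted over the list alone, 1700020I14Rik stood at 217 ± 23.5 CPM, and the median of −0.20 lay at percentile 3.69. Blood genes were scarce, with Hbb-bs at 13.4 ± 3.69, Hba-a1 at 9.83 ± 1.46 and Hba-a2 at 8.48 ± 3.38 CPM. None of the 4 measured blood genes passed over all genes or when adjusted over the list alone, and their median was −0.49, at percentile 6.78. Of the sex-linked list, Xist, expressed from the inactive X chromosome, was the 1 member measured, at 18.1 ± 0.731 CPM (SD, n = 2), with a log2 ratio of −0.07, at percentile 43.5, and did not pass in either adjustment. Ddx3y, Uty, Kdm5d and Eif2s3y of the Y chromosome had 0 reads in both libraries. In the isoform list, chosen for genes with known alternative transcripts, 22 of 83 measured genes were higher in replicate 2 and 9 in replicate 1, 43 passed when adjusted over the list alone, and the median was 0.08, at percentile 99.5. Of those in no other list, Pkm, Map2, Kif1b, Ncam1, Ntrk2, Rtn1, Actb and Ndrg2 were higher in replicate 2 and Calm2, Ndrg4, Srsf5 and Tpm1 in replicate 1 (exact binomial tests).

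**Figure D2:**
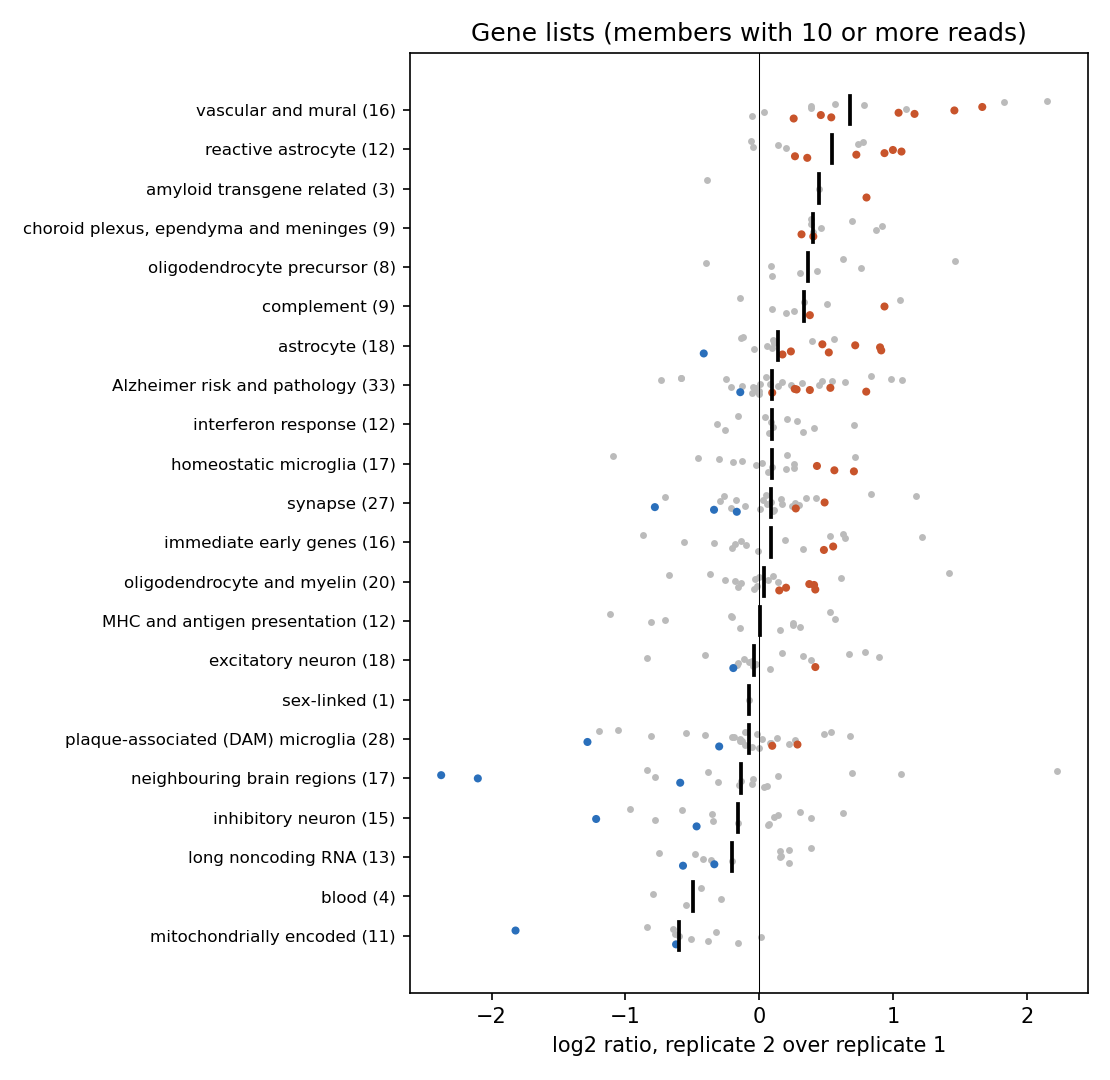
The log2 ratio of replicate 2 over replicate 1 for each list member with 10 or more reads, 1 point per gene, grouped by list with the number measured, black bars marking medians. Orange points were higher in replicate 2 and blue points higher in replicate 1 by the exact binomial test, and vascular (median 0.68) and mitochondrially encoded genes (median −0.60) stand at the ends.

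In these lists, 71 genes passed the exact binomial test, and 3 of them (Doc2g, Th and Spp1) also passed edgeR's negative binomial exact test, which adds the spread between the libraries as estimated from the same libraries. Atp1a2 had an adjusted p of 0.0899 and Slco1a4 of 0.077 in that edgeR test. With the reads of known transcripts alone, 14 of the 71 no longer passed. Among these the log2 ratio stayed about as large in Dlx1 (−1.19 from −1.22), Acta2 (1.55 from 1.67), Adora2a (−0.77 from −0.59), Aplp2 (0.34 from 0.27), Ntrk2 and Tpm1. It was smaller in Slco1a4 (0.84 from 1.16), Egr1 (0.12 from 0.55), Meg3, Snhg11, Ndrg2 and Srsf5, turned in Map2 (−0.74 from 0.49), and Ncam1 had too few reads. After thinning of the deeper library 9 did not pass, namely Ctsb, Glul, Ptgds, Gbp2, Rgs5, Acta2, Snhg11, Actb and Tpm1. Their log2 ratios kept their sign and stayed about as large, as in Ptgds (0.21 from 0.27) and Acta2 (1.42 from 1.67). After removal of the trend with transcript length 5 did not, Gria3 (0.42 from 0.49), Rgs5 (0.43 from 0.46), Egr1 (0.51 from 0.55), Ntrk2 (0.24 from 0.33) and Ctsb (0.04 from 0.10). Among members that still passed, the log2 ratio also moved by over 1.5 times in Ptgds with that trend removed (0.46 from 0.27), and with known transcripts alone in Mag (0.81 from 0.37) and Kif1b (1.69 from 0.66). Spp1, Doc2g, Trf, Aldh1l1, Glul, Gria3, Stat1, Meg3, Snhg11, mt-Co3 and Xist overlap another annotated gene on the same strand, and Hba-a1, Hba-a2, H2-D1 and H2-K1 have near-identical copies, so their counts are uncertain.

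Both libraries detected largely the same genes. At least 1 read was found for 18622 annotated genes in replicate 1 and 17606 in replicate 2, and 16138 genes, 80.3% of the 20090 seen in either, were found in both. Across 12902 genes with at least 10 reads over both libraries, the log2(CPM + 1) values had Pearson r = 0.966 and Spearman rho = 0.964, where counting error alone gave 0.978 and 0.976. These correlations are across genes, which are not independent replicates. The biological coefficient of variation, edgeR's common dispersion on the square root scale, was 0.118. The exact binomial test found 537 of 12902 genes to differ between the libraries at an adjusted p under 0.05, 292 higher in replicate 2 and 245 higher in replicate 1. With edgeR's negative binomial exact test there were 33, of which 9 were higher in replicate 2 and 24 in replicate 1.

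Omp, the marker of mature olfactory sensory neurons (chromosome 7 of mm10, 98143359–98145502), had 45 reads in replicate 1 and 0 in replicate 2 (exact binomial adjusted p = 2.11e-09). Against a floor of 3 reads for the count of 0, Omp was 11.5-fold higher in replicate 1. Ratios against this floor leave out the counting error of the reads in replicate 1, so they are not lower bounds. Other genes with the largest ratios in favour of replicate 1 included the pseudogene Gm3365 (34 and 0 reads, 8.67-fold against the floor) and Ms4a15 (16 and 0 reads, 4.08-fold against the floor). Frmd7 (46 and 1 reads), Cd46 (24 and 1 reads) and BC065397, a noncoding transcript upstream of Plp1, with 375 and 5 reads, were also among them. In favour of replicate 2 stood Gm2004 (1 and 27 reads), Sema3b (4 and 19), the protease inhibitor gene A2m (4 and 17), the adrenergic receptor gene Adra1b (5 and 19), Chd1 (1 and 11) and the pseudogene Ppp1ccb (1 and 10). The CPM of Frmd7 was 35.2 times higher in replicate 1 (exact 95% interval 6.01–1419) and that of Cd46 18.4 times (2.99–755). In replicate 2, Gm2004 was 35.3 times higher (5.82–1446), Chd1 14.4 times (2.09–619) and Ppp1ccb 13.1 times (1.86–568). Gm45021, 3110053B16Rik, Tmc4, Hgs, Chtf8, Gm20427, Pcdhga2 and Tkfc complete the 20 genes with the largest ratios. These 8 no longer passed when genes with overlapping exons on the same strand were counted as 1 locus, and 7 of them overlap such a gene, so their counts are uncertain. Gm3365, Gm2004 and Ppp1ccb belong to families of similar sequences, which leaves their counts uncertain too. BC065397, Gm3365, Cd46, A2m, Chd1, Gm45021, 3110053B16Rik and Gm20427 had no reads on known transcripts in either library. Their counts rest on ISM, NIC, NNC or genomic models and are uncertain as well. Of the 20 genes, 12 also passed edgeR's negative binomial exact test. Among these were Gm45021, 3110053B16Rik, Tmc4, Hgs, Gm20427 and Pcdhga2, which no longer passed the binomial test as 1 locus.

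**Figure D3:**
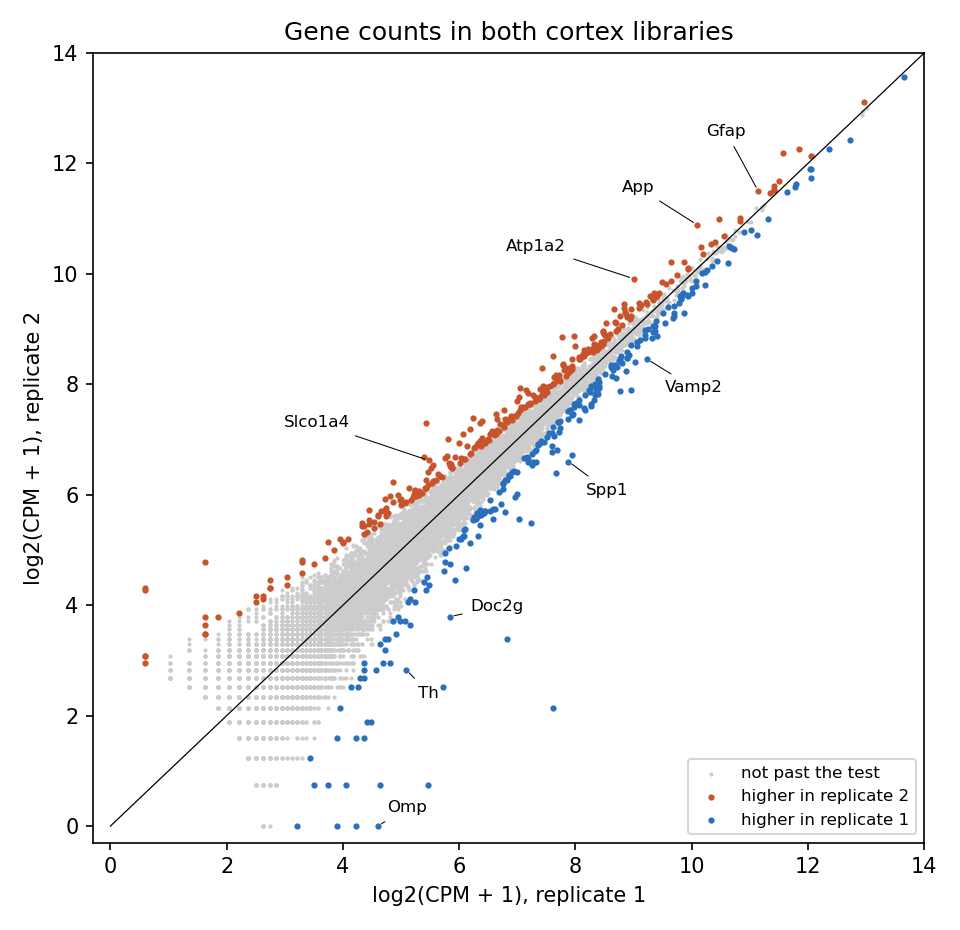
log2(CPM + 1) of each of 12902 annotated genes in replicate 1 (x axis) and replicate 2 (y axis), 1 point per gene, with a diagonal line for equal values. The 292 genes higher in replicate 2 by the exact binomial test are orange and the 245 higher in replicate 1 are blue, with App, Gfap and Atp1a2 above the line and Spp1, Doc2g, Th and Omp below it.

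Most reads came from annotated transcripts. Known transcripts took 75.4 ± 0.0295% of reads (SD, n = 2), and 96.6 ± 0.223% of known reads fell on protein-coding transcripts. Models with an incomplete splice match (ISM), which hold part of an annotated chain of introns, took 8.63 ± 0.454%. Unannotated combinations of annotated splice sites (NIC) took 7.02 ± 0.239%, and models with an unannotated splice site (NNC) took 4.10 ± 0.0685%. Antisense, intergenic and genomic models took 1.69 ± 0.138%, 0.263 ± 0.0212% and 2.85 ± 0.154%. The ISM share of genes by known transcript length was 6.93% and 8.18% in replicates 1 and 2 under 1000 nt, lowest from 1000 to 2000 nt with 4.26% and 4.19%, and highest above 5000 nt with 19.6% and 22.0%.

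Of 6843 genes with at least 20 full-length reads in each library, 73.8% had 2 or more isoforms of at least 5 reads, and the dominant isoform was annotated in 92.7%. All 30 named genes of the isoform list had the same dominant isoform in both libraries, and its share had a median of 85.0 ± 0.669% (SD of the library medians, n = 2), over 80% in 20 of the genes and under 50% in 3. Cst3, Calm2, Calm1, Ctsd, Cplx1, Ctsb, Actb and Apoe were close to single isoforms, with Cst3-201 at 99.6 ± 0.16% and Apoe-206 at 97.6 ± 0.244%. Gfap-201, the main glial filament isoform, took 89.2 ± 0.189% and Snap25-201 took 89.1 ± 2.01%, with Snap25-202, which carries the alternative copy of an exon, at 9.01 ± 2.11%. Mbp-211 took 80.5 ± 1.02% of Mbp reads and Mbp-212 took 11.2 ± 0.895%, while Plp1-201 took 72.9 ± 1.06% and Plp1-202 25.3 ± 1.37%. Pkm-202 and Pkm-201, the alternative forms of pyruvate kinase, took 84.1 ± 1.29% and 13.6 ± 0.956%. Gria2 was split between Gria2-201 at 48.8 ± 1.70% and Gria2-202 at 27.4 ± 3.6%, and Bin1 between the 13-exon Bin1-205 at 30.5 ± 0.16% and the 19-exon Bin1-201 at 26.4 ± 0.789%. Mapt-204, with 10 exons, took 67.4 ± 8.48% of the reads of tau and the 12-exon Mapt-201 took 12.4 ± 2.73%. Clu-201 took 82.3 ± 4.75%, and Meg3 alone had an unannotated dominant chain, at 31.8 ± 4.68%.

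**Figure D4:**
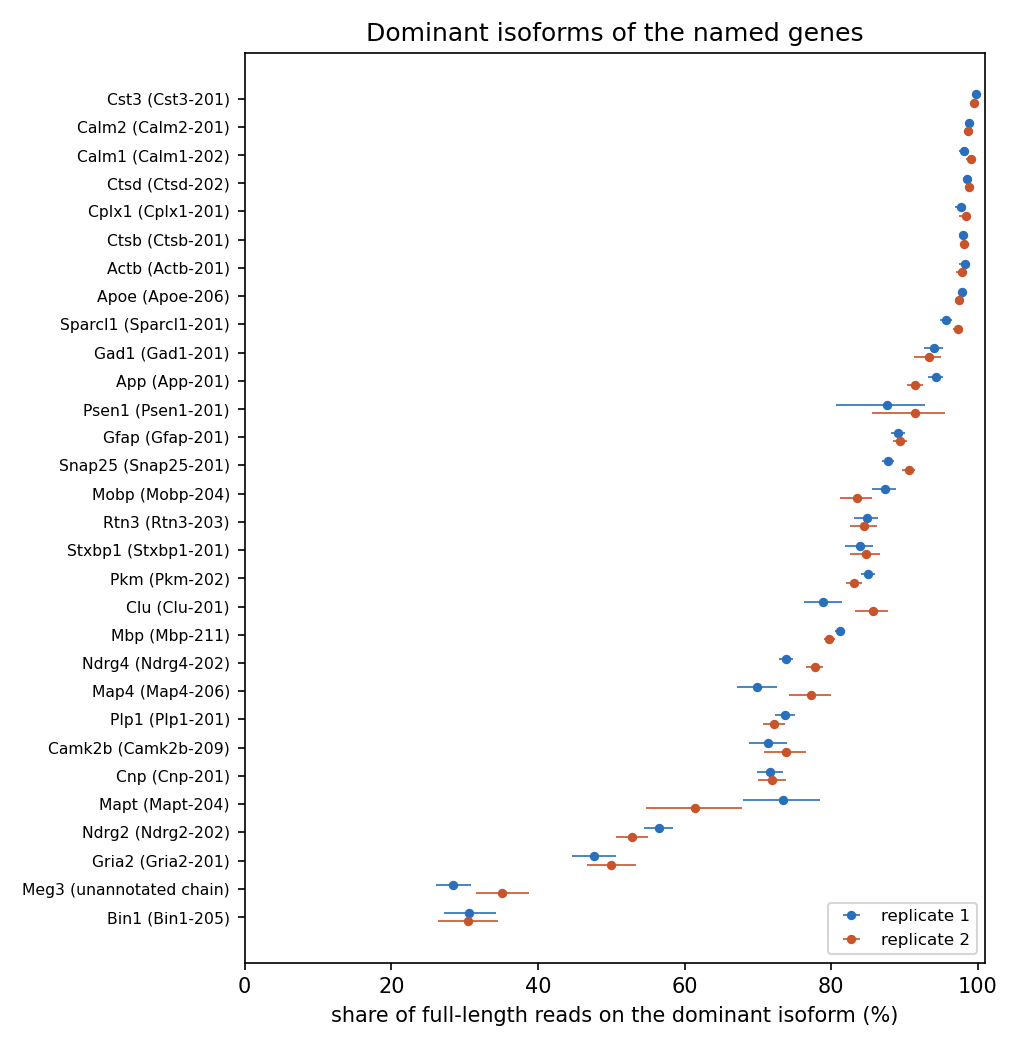
Share of full-length reads (%) on the dominant isoform of each of the 30 named genes, with 1 point per library and horizontal lines for exact Clopper-Pearson 95% intervals. Shares run from 99.6% for Cst3 to 30.5% for Bin1, and the same isoform was dominant in both libraries.

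Isoform proportions differed between the libraries in 117 of 4618 genes (Monte Carlo permutation of a chi-square statistic, adjusted p under 0.05), of which 454 had an unadjusted p under 0.05. In Atp2b1, Cops7a, Dctn1, Gprasp1 and Ash1l the chain that moved most was counted as full-length in replicate 2 and had been classed as ISM in replicate 1. Dctn1, a dynactin subunit, had 245 and 230 reads on that 26-exon chain, and the 8-exon chain of the signalosome subunit Cops7a had 457 and 331. With a chain taken as full-length in both libraries where it was so in either, 21 genes passed, 20 of them among the 117. Atp2b1 (adjusted p = 0.0288) and Gprasp1 (adjusted p = 0.0245, Monte Carlo permutation tests) still passed, as did Gprasp2 and Hgs, whereas Cops7a, Dctn1 and Ash1l did not. Gpsm1 also passed in that setting (adjusted p = 0.00357, the value reached by the smallest p the permutation draws can give, 1e-05). Its 4-exon Gpsm1-211 had 73.6% of full-length reads in replicate 1 and 14% in replicate 2. The connexin gene Gjb6 and Cyb5d1, with 78.6% and 59.3% of reads on their first annotated isoform in replicate 2 against 100% of 165 and 34 reads in replicate 1, did not pass in that setting. With overlapping genes counted as 1 locus Hgs no longer passed (adjusted p = 0.75) and Gprasp2 still did (adjusted p = 0.000871, Monte Carlo permutation tests). The 7-exon chain with 138 reads on Gprasp2 in replicate 1 had 127 reads on Bhlhb9 in replicate 2. Of the 30 named isoform genes, 7 passed the main test, among them Snap25, Ndrg4, Plp1 and Gria2, and Snap25-202 took 10.5% of tested reads in replicate 1 and 7.55% in replicate 2. Plp1-201 and Plp1-202 took 73.7% and 26.3% of full-length Plp1 reads in replicate 1, and 72.2% and 24.4% in replicate 2. Since 20 of the 117 still passed with the class taken from either library, calls in these 7 genes may also rest on the class of a chain. With known transcripts alone 7 genes passed, and with ISM reads included 72, of which 28 are among the 117.

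Several chains that match no annotated transcript took large shares of their genes' full-length reads in both libraries. A 5-exon NIC chain of Oaz1, the ornithine decarboxylase antizyme gene (chromosome 10 of mm10, 80826656–80829284), held 1919 and 1152 reads and 97.2 ± 0.291% of full-length reads (SD, n = 2), and a 5-exon chain of its relative Oaz2 held 1265 and 881 reads and 93.0 ± 0.792%. Both lacked an annotated intron of 1 base, at 80828295 in Oaz1 and at 65686272 on chromosome 9 in Oaz2. This was their only difference in introns from the annotated Oaz1-207 and Oaz2-206. Neither held an unannotated intron, so these chains are no evidence of unannotated splicing. Penk, the enkephalin precursor gene (chromosome 4, 4133068–4138819), had a 3-exon NNC chain with 98.0 ± 0.630%, with an unannotated intron at 4138147–4138634. Apbb1, whose product binds the intracellular tail of the amyloid precursor protein, had a 14-exon chain with 57.3 ± 2.10% (chromosome 7, 105558483–105581278). Rapgef4, a cAMP-activated exchange factor, had 29- and 30-exon chains with 46.9 ± 0.784% and 45.4 ± 1.23%. Chains of Dctn2, Chmp1a, Sept7 and Cct6a took 84.3 ± 0.923%, 91.0 ± 0.324%, 80 ± 8.65% and 88.7 ± 1.24%. The Rapgef4 and Sept7 chains lack a short annotated exon, flanked by introns ending at 72141152 and 25265301 and starting at 72141173 and 25265307. Misalignment at such short exons was not tested. Of all unannotated multi-exon chains of one library, 32.0 ± 5.86% were found with identical introns in the other, and 97.3 ± 2.27% of those with at least 5 reads.

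Cassette exons were counted in 20188 events with at least 10 informative reads in each library, each for 1 pair of flanking splice sites, and 3064 had a mean inclusion from 10 to 90%. Across these 3064 the inclusion in the libraries had Pearson r = 0.918. Myelin and neuronal genes of the isoform list gave the following levels. The 123-nt exon of Mbp (chromosome 18 of mm10, 82578936–82579058) was included in 12.6 ± 0.994% of reads (SD, n = 2), the 45-nt exon of Mag (chromosome 7, 30900352–30900396) in 75 ± 2.92% and its 53-nt exon (30914269–30914321) in 18.7 ± 1.40%. Camk2b included a 45-nt exon in 87.0 ± 0.857%, Stxbp1 a 126-nt exon in 12.7 ± 0.0406%, Ndrg2 a 42-nt exon in 22.9 ± 1.83%, Meg3 an 81-nt exon in 18.5 ± 1.96%, Bin1 a 93-nt exon in 55.1 ± 0.687% and Clta a 36-nt exon in 85.2 ± 0.0309%. Aplp2 included its 36-nt exon in 83.7 ± 1.60% and its 168-nt exon, which encodes a Kunitz domain, in 82.6 ± 1.25%. The 24-nt microexon of the GABA receptor subunit gene Gabrg2 (chromosome 11, 41913970–41913993) was included in 65.7 ± 2.02%, that of Mef2c (chromosome 13, 83654598–83654621) in 94.2 ± 0.611% and that of Pak1 in 4.02 ± 0.559%. Of the other microexons with the most informative reads, those of Bsg, Ppp1r1b and Aplp1 were included in over 99% of reads. Those of Mbp, M6pr, Dstn, Nap1l4 and Syt16 were included in under 1%. They were held by at most 2 reads in a library, the rest being reads that skip them, so they are no evidence of microexons in use. The exons of Pak1, Mbp, Dstn, Nap1l4 and Syt16 match no annotated exon.

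Inclusion differed between the libraries in 3 of the 20188 events by Fisher's exact test, with 285 at an unadjusted p under 0.05. Recovery of real shifts was not simulated for these events, so the count of 3 does not show that shifts were few. The 39-nt exon of Ndrg4 (chromosome 8 of mm10, 95712325–95712363) was included in 91.0% of 7812 reads in replicate 1 and 93.9% of 5396 in replicate 2 (Fisher's exact test, adjusted p = 2.8e-05). The 60-nt exon of the dynein gene Dync1i1 (chromosome 6, 5784439–5784498) was included in 74.3% and 91.1% (Fisher's exact test, adjusted p = 5.2e-05), and the 77-nt exon of Pcbp3 (chromosome 10, 76847736–76847812) in 24.9% and 7.84% (Fisher's exact test, adjusted p = 0.029).

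Outside annotated genes, the most abundant antisense locus lay opposite Snhg11 (chromosome 2 of mm10, 158381590–158384917) with 260 ± 38.7 reads per 1000000 (SD, n = 2). Those opposite AI593442, Tmem170b, Map1b and Rab11fip4 followed with 168 ± 21.6, 167 ± 15.3, 159 ± 25.8 and 135 ± 21.2 reads per 1000000. Of 17841 antisense loci, 4825 had reads in both libraries. The most abundant intergenic locus lay 2078 bases from Efna5 (chromosome 17, 62883395–62886936) with 23 ± 6.0 reads per 1000000, and the next, 595 bases from S1pr3 (chromosome 13, 51423392–51426106), had 20.5 ± 1.06. Loci at a distance of 0 bases from Klhl10, Gm12671 and Klhl34, the last on the opposite strand, had 70 and 0, 0 and 55, and 0 and 48 reads in replicates 1 and 2. Classes were given in each library separately. A count of 0 therefore allows up to 3 reads of this class only, and whether reads there were classed otherwise was not tested. Of 5117 intergenic loci, 726 had reads in both libraries. All 10 of these loci held single-exon models, and such models took 95.7% and 95.9% of all antisense reads in replicates 1 and 2. These have no splice site to give their strand, and the handling of strand is not given. Antisense transcripts therefore cannot be told apart here from wrongly oriented reads of the genes opposite.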

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

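Reads outside annotated genes lie outside the gene comparisons. On chromosome Y, replicate 1 held 5 such reads, from 4 transcripts at 2 loci, above the limit of 3 reads that a count of 0 allows. Replicate 2 held 0, which allows up to 3, and annotated Y genes had 0 reads in both libraries.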

How the results depend on the processing

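The counting of overlapping genes as 1 locus, the removal of the length trend and the class taken from either library were chosen only after the results were seen. Of the 537 genes that differed by counting error, edgeR's negative binomial exact test, which adds the spread between the libraries, called 33. Other settings gave from 429 (known transcripts only) to 561 (at least 50 reads), within 1.5 times of 537. Of the 71 list members past the binomial test, 50 passed under all settings other than the negative binomial test. Of members that still passed, the log2 ratio moved by over 1.5 times in Fth1, Cst3 and Ptgds with the length trend removed, and in Mag and Kif1b with known transcripts only. Isoform usage rested on the class of each chain, since 117 genes passed as planned, 21 with the class taken from either library (20 of them among the 117), 7 with known transcripts only (7 among them) and 72 with ISM reads included (28 among them). In 56 of the 117 the chain that moved most was in a class left out in 1 library. At the depth of these libraries the binomial test recovered 17.5% of simulated 1.5-fold changes in genes drawn from all read counts, so most such changes were missed. Detection depends on the read count, and abundant genes passed at far smaller ratios, such as Hspa8 (log2 ratio −0.09) and Eef2 (0.08).

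Transcripts with at least 5 reads raised the known share to 85.0% and lowered ISM, NIC and NNC to 5.59%, 4.84% and 1.65%. Asking for at least 10 reads left 10364 genes detected in both libraries. A pseudocount of 5 raised the correlation to 0.977, and the other settings gave 0.956 to 0.969. The change that counts as moved there was set after the values were seen. The median dominant share was 82.0% with ISM reads and 95.3% with known transcripts only, and 85.2–86.1% with each replicate left out, as replicate medians differ from the median of mean shares. Singly, 21 of 30 dominant shares moved with ISM reads and 28 of 30 with known transcripts only. Shared unannotated chains rose from 32.0% to 45.9% with splice sites within 10 bases, 73.8% from 2 reads and 97.3% from 5 reads. Cassette exons at 10 to 90% inclusion numbered 1951 with at least 20 reads and 764 with known transcripts only, where fewer events qualify, and 3148–3205 with each replicate left out. Differing cassettes numbered 7 without ISM reads and 3 otherwise. For these changes the cause was not tested, beyond what a higher minimum or fewer classes removes by construction.

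The coefficient of variation stayed between 0.113 and 0.118. Of list medians, 23 of 23 kept their side of the percentile bounds with TMM, 19 of 22 with at least 50 reads and 21 of 23 with the length trend removed. With at least 50 reads the Alzheimer list moved out (0.14, percentile 99.2), as did long noncoding RNA (−0.33, percentile 0.26). Both weakened with the length trend removed, to 0.05 (percentile 83.75) and −0.07 (percentile 27.3). Oligodendrocyte precursors moved inside with at least 50 reads (0.31, percentile 94.4) and with the length trend removed (0.33, percentile 96.4), where homeostatic microglia moved out (0.19, percentile 99.3). No median outside the bounds changed sign, and that of immediate early genes, inside them, went from 0.09 to −0.09 (percentile 15.8) with at least 50 reads. Of the 20 genes with the largest differences, 8 no longer passed with overlapping genes counted as 1 locus. These were 87.5% of the 8 that overlap another gene, and Tkfc, which overlaps none and moved to a binomial adjusted p of 0.0503 through the adjustment alone. For the 12 that overlap none the merging tests nothing. No paired analysis was possible because the labels give 1 group. Tests between the libraries cannot be run with 1 of them left out.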

Other observations

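The comparison of exon lengths, the tests of length and of transgene reads for App, and the astrocyte test for App were chosen only after the results were seen. An exon whose length is a multiple of 3 keeps the reading frame when it is skipped. Among microexons of 27 nt or less, 78 of 87 with 10 to 90% inclusion had such a length (89.7%, exact 95% interval 81.3–95.2%), against 109 of 203 with lower or higher inclusion (53.7%, Fisher's exact test, p = 7.7e-10). The shares were 52.1% of 2002 against 39.8% of 11704 for exons of 28 to 150 nt (Fisher's exact test, p = 1.06e-24) and 42.8% of 603 against 36.6% of 4609 for longer ones (p = 0.00362, Fisher's exact test). Exons of 1 gene are not independent, and annotated and unannotated exons were not separated.

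Omp, Th and Doc2g were higher in replicate 1, and 3 of 3 still passed after replicate 1 was thinned (highest binomial adjusted p = 2.64e-05). The test already scales by the gene totals, and this thinning could hardly end calls this large. It therefore cannot decide on a difference in library depth. A separate list of 20 olfactory bulb markers, written before its test, had a median log2 ratio of −0.62, at percentile 0 of the matched random lists. All 12 measured had the higher value in replicate 1, and Synpr (393 and 282 CPM), Meis2 (264 and 162 CPM) and Dlx2 passed. Cortex also expresses many of them, as 9 of the 12 had at least 10 reads in replicate 2, and 1 of the 20, Eomes, is in another list. These values are consistent with olfactory bulb tissue in the first library, replicate 1, as a hypothesis, and a difference between animals was not tested, since there is 1 group.

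App (log2 ratio 0.80), 7 of 18 astrocyte genes and 7 of 16 vascular genes were higher in replicate 2 and the astrocyte gene Cst3 was lower (exact binomial tests), and none of these passed edgeR's negative binomial exact test. With the trend on transcript length removed App stood at 0.79, against 0.80 ± 0.04 before. Median log2 ratios by length ran only from −0.26 under 1000 nt to 0.08 above 5000 nt. Removing such a trend could hardly lower a ratio this large. It shows that the fitted trend is far smaller than the App ratio, and it tests no other effect of length. Reads of the human cDNA counted as App are argued against as the whole cause, because App chains other than App-201 were 2.28 times higher (exact 95% interval 1.83–2.87) and reads with the 168-nt Kunitz exon, which that cDNA lacks, 2.89 times (2.13–3.97). A larger share of astrocytes alone would raise genes expressed only in astrocytes by at least as much as App. The astrocyte list's median of 0.14 lies below App by more than the SD of the members (0.365), with 16 of 18 below App and Atp1a2 and Slc1a2 above. This argues against that share as the whole cause for App only so far as the members are expressed in astrocytes alone, which was not measured here. The source of the App, astrocyte and vascular differences stays open, an astrocyte share was not tested for the astrocyte genes themselves, and a difference between animals was not tested, since there is 1 group.

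Reads of the transgenes are a hypothesis for the ends seen in Thy1 and Psen1. The single-exon share of Thy1, 50.5% and 70.5%, lay at percentiles 99.8 and 99.97 of 3152 genes with medians of 1.06% and 1.02%, as transcripts that end in the Thy1 cassette could give, although Macrod1, Phactr1, Cpsf7 and Strbp, which are no part of it, had shares from 62.4% to 98%. For the Psen1 chain that stops before the end of the coding region, the test asked whether ends shared by both libraries are rare in other genes, and 278 of 635 incomplete chains with an internal 3' end shared both ends within 5 bases (43.8%, exact 95% interval 39.9–47.7%). This set was redefined after a first result, from chains with both ends internal, because the Psen1 chain itself starts at an annotated exon start. The bound of 25% set beforehand against the hypothesis was wrong, since shared ends in genes without a transgene do not exclude human reads on Psen1, so the sources of that chain cannot be told apart without the transgene sequence.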
